A study of Homo sapiens with 14 samples.

How the data were processed

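Expression was measured on 14 Illumina bead arrays hybridized with biotin-labelled total RNA from the prostate cancer lines LNCaP, 22RV1 and PC-3M. Probe values were produced in GenomeStudio, whose version was not given, per the submitters' processing notes. Per the labels' protocols, the LNCaP shRNA arrays were processed at another core facility than the siRNA, 22RV1 and PC-3M arrays. In the deposited table of the 8 LNCaP shRNA arrays and in that of the 2 PC-3M arrays, values were probe intensity after background subtraction, with values below 0, and were not normalized between arrays. In the deposited table of the 4 siRNA and 22RV1 arrays, values were raw probe intensity with a floor well above 0. The deposited LNCaP shRNA and PC-3M tables also held a detection p-value of each probe against negative controls, per the file headers. In the siRNA and 22RV1 table the columns headed as detection p-value, per the file headers, held whole numbers, which p-values cannot be; they were read as numbers of beads per probe and were not used. A deposited matrix of all 14 arrays held linear intensity that the sorted values showed to be quantile normalized in 3 sets: the 4 numbered LNCaP shRNA arrays, the R1881 and hormone-deprived arrays together with the PC-3M arrays, and the siRNA and 22RV1 arrays. That matrix served only as an alternative source of values.

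Each of the 3 tables was processed by itself in R 4.3.3 with limma 3.58.1. The background mean and SD of each array were inferred from the detection p-values, the normal-exponential correction was applied with an offset of 16, and arrays were quantile normalized on the log2 scale. For the siRNA and 22RV1 table, the background was taken from the mode of the intensities and the spread below it, and a probe counted as detected above the mode plus 1.645 SD; this rule was chosen after seeing the values. On the 10 arrays that have detection p-values, the same rule gave the same call for 91.4 to 99.5% of probes. Elsewhere a probe counted as detected at a detection p below 0.05.

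The tables held 47323 probes, of which 30113 carried 1 gene symbol in the platform annotation, 8 carried several and 17202 were not listed, which left 20046 named genes. Symbols were compared with the RefSeq table of GRCh38.p14, in which the gene IDs of 30074 probes were found, and 0 symbols were changed. No coordinates are printed because the files name no genome build. Each gene was represented by its probe with the highest mean within each table, except that models were compared on the probe of the LNCaP shRNA fit. Of the 364 members written for the gene lists, 32 had no named probe.

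The main comparison was a limma fit (lmFit, eBayes) to the 8 LNCaP shRNA arrays with knockdown and medium as terms, two-sided, with Benjamini-Hochberg adjusted p below 0.05. The medium term had 3 labels: not named, R1881 and hormone-deprived. Below, 3 media means these labels, since the medium not named may be R1881. Probes detected on at least 2 of the 8 arrays were kept, which gave 22177 probes and 11892 genes. The residual had 4 degrees of freedom and the prior 4.41. That residual held the spread of the numbered replicates and also the differences in knockdown effect between media, which have no replicates. The numbered replicates alone were compared as a contrast of a fit with 6 group means, which had 2 residual degrees of freedom, all from these replicates, and the same fit tested the difference between media. For gene lists, camera was run with a preset correlation of 0.01, and again with an estimated correlation, with fry beside it. The 19 lists were written before the data were examined, as were the comparisons and the alternatives not said to be added; 18 lists were tested, since the basal list had only 2 measured members in that fit. All other comparisons had 1 array per group and were given no test of their own. There, genes at least 2-fold apart and detected on the brighter array were counted, and a list's median was placed among 10000 random lists of the same size matched on mean expression. Where the dimmer group was undetected on all of its arrays, the fold was also computed against its detection limit and is given as a lower bound.

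Named genes followed a rule fixed before the data were examined. It took FOXA1, KLK3, SNAI2, CDH1 and VIM throughout, and 1 more gene that is not reported here. From the LNCaP shRNA fit it took the 6 largest increases and the 6 largest decreases past the test with 1 sign in all 4 pairs. It took the 4 largest differences each way from each comparison of single arrays, and up to 4 members of each list. It also took genes that passed the test in LNCaP, were at least 2-fold apart the same way in the siRNA and 22RV1 pairs, and at least 2-fold apart the other way in PC-3M. Pairs join arrays with the same medium label or, for the numbered arrays, the same number. The deviations of same-numbered arrays from their group means correlated at -0.173, which gives no sign that the numbers pair them.

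The fit and the list tests were tested on simulated data made from the 11892 genes of the LNCaP shRNA fit over 3 media. With 200 genes changed, 73.3% of 2-fold and 95.7% of 4-fold changes were recovered over 20 runs, all in the right direction, with 7.5 false calls per run on average. A planted list of 20 genes was called in 20 of 20 runs and an unchanged list in 0. Noise was drawn for each gene by itself, with the same SD on all 8 arrays. These runs therefore do not test list calls among correlated genes, nor gene calls where arrays differ in spread. In the real data the estimated correlation reached 0.939, in the G2/M list. The SD of the differences over all genes was 0.807 in the replicate 1 pair and 0.362 to 0.52 in the other pairs.

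Probes were detected at 34.3 to 42.6% on the LNCaP shRNA arrays, 48.8 to 51.9% on the siRNA arrays, 47.1 to 52.7% on the 22RV1 arrays and 39.6 to 41.3% on the PC-3M arrays; the siRNA and 22RV1 shares rest on the other detection rule. The number of arrays limits the precision. Alternatives covered background correction, normalization, offset, filter, probe choice, thresholds, left-out arrays and pairs, array weights, blocks and the deposited matrix. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.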

Results

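The study asked what the transcription factor FoxA1, which opens chromatin for other factors, controls in prostate cancer cells. LNCaP, an androgen-sensitive line, carried a control shRNA (shCtrl, 4 arrays) or a FoxA1 shRNA (shFoxA1, 4 arrays). In each of these groups 2 numbered replicates have no medium in their titles, 1 array is labelled R1881, a synthetic androgen, and 1 is labelled hormone-deprived; the descriptions call the R1881 arrays replicate 3. The protocol, worded alike for all 8 arrays, names 3 days in charcoal-stripped medium and 1 nM R1881 for 24 hours in some experiments. The other groups had 1 array each: LNCaP with control or FoxA1 siRNA, 22RV1 with control or FoxA1 shRNA, and PC-3M, a metastatic line, as control or labelled FoxA1. Mean intensity was 157 to 285 on the LNCaP shRNA arrays, 436 to 447 on the siRNA arrays, 235 to 325 on the 22RV1 arrays and 208 to 222 on the PC-3M arrays. Nothing in the labels says that numbered replicates came from separate cultures, so the p-values measure only the spread between arrays. In the fit over the 3 media this spread also holds the unreplicated differences in knockdown effect between media.

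FOXA1 itself was lower in every knockdown pair. In the LNCaP shRNA arrays it fell by 1.02 on the log2 scale (SE 0.15, n = 4 against 4, limma adjusted p = 0.0127), and the log2 difference was -1.10 and -1.28 in replicates 1 and 2, -0.98 with R1881 and -0.73 in hormone-deprived medium. It was -0.81 in the siRNA pair and -1.11 in the 22RV1 pair. In PC-3M, where the labels name overexpression, FOXA1 was -1.51 on the array labelled FoxA1, from a log2 intensity of 10.4 to 8.89, against the label. All of these values come from 1 probe (ILMN_1766650), whose position in the transcript is not given in the sources used here. Left without the R1881 pair, the LNCaP difference was -1.04 with an adjusted p of 0.0678, and without the medium term it was -1.02 with an adjusted p of 0.0554; over the other settings the adjusted p lay between 0.00282 and 0.0453.

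The main comparison asked which genes change with FoxA1 knockdown in LNCaP over the 3 media. The largest increases were in S1PR3, a receptor for sphingosine 1-phosphate, at 21.4-fold (log2 4.42, SE 0.44, n = 4 against 4, adjusted p = 0.00386), in PI3, the protease inhibitor elafin, at 14.3-fold (log2 3.84, SE 0.78, adjusted p = 0.0284), and in S100A9, a calcium-binding protein of myeloid cells, which was undetected in shCtrl and at least 12.3-fold higher (log2 3.80, SE 0.86, adjusted p = 0.0372). RTN1, a reticulon of the endoplasmic reticulum, rose by 3.40 (SE 0.35), PIP, the prolactin-induced protein, by 3.31 (SE 0.80), and CRYAB, a small heat shock protein, by 3.13 (SE 0.32), with adjusted p of 0.00413, 0.0434 and 0.00386. The largest decreases were in DDC, the DOPA decarboxylase, which fell by 3.06 (SE 0.27, adjusted p = 0.00297), the relaxins RLN1 (-2.82, SE 0.15, adjusted p = 0.000391) and RLN2 (-2.47, SE 0.21, adjusted p = 0.0028), and the prostate protein SLC45A3, or prostein (-2.66, SE 0.29, adjusted p = 0.00446). ARG2, a mitochondrial arginase, fell by 2.22 (SE 0.16) and MCCC2, an enzyme of leucine breakdown, fell by 2.05 (SE 0.17), with adjusted p of 0.00214 and 0.0028. DDC, RLN1, RLN2 and ARG2 were undetected on both numbered shFoxA1 arrays, where background limits the size and spread of their differences. On the numbered replicates they were at least 6.7-fold, 4.0-fold, 4.8-fold and 3.7-fold lower. All 6 increases were largest in the replicate 1 pair, PI3 and PIP at 7.40 and 6.79 against 3.13 and 3.11 in the replicate 2 pair, and RTN1 and CRYAB at 4.79 and 4.54 against 3.64 and 2.97. Without replicate 1, PI3 was 2.65 higher (adjusted p = 0.000874), S100A9 2.58 (adjusted p = 0.0148) and PIP 2.16 (adjusted p = 0.0235), and PIP differed by only 0.67 in the hormone-deprived pair.

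In all, 939 of 11892 genes passed the test, 494 higher and 445 lower, and 934 of them had 1 sign in all 4 pairs. Of these, 313 were at least 2-fold apart, 183 higher and 130 lower. The count was 52 without the R1881 pair, 214 without shCtrl replicate 1, 133 without shCtrl replicate 2, 121 without shFoxA1 replicate 2, 123 without the medium term, 265 with no filter and 188 from the deposited matrix. With median scaling alone, which moved the median of all genes to -0.15, it was 1456, of which 247 were higher and 1209 lower. The R1881 and hormone-deprived pairs by themselves, which the deposited matrix normalized apart from the numbered replicates, gave 740 genes. That fit had 1 residual degree of freedom, the difference in knockdown effect between these pairs, and no replicate of any group. The differences of these pairs and of the numbered replicates had a Pearson correlation of 0.64 and a Spearman correlation of 0.525 across genes, which are not independent replicates.

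**Figure D1:**
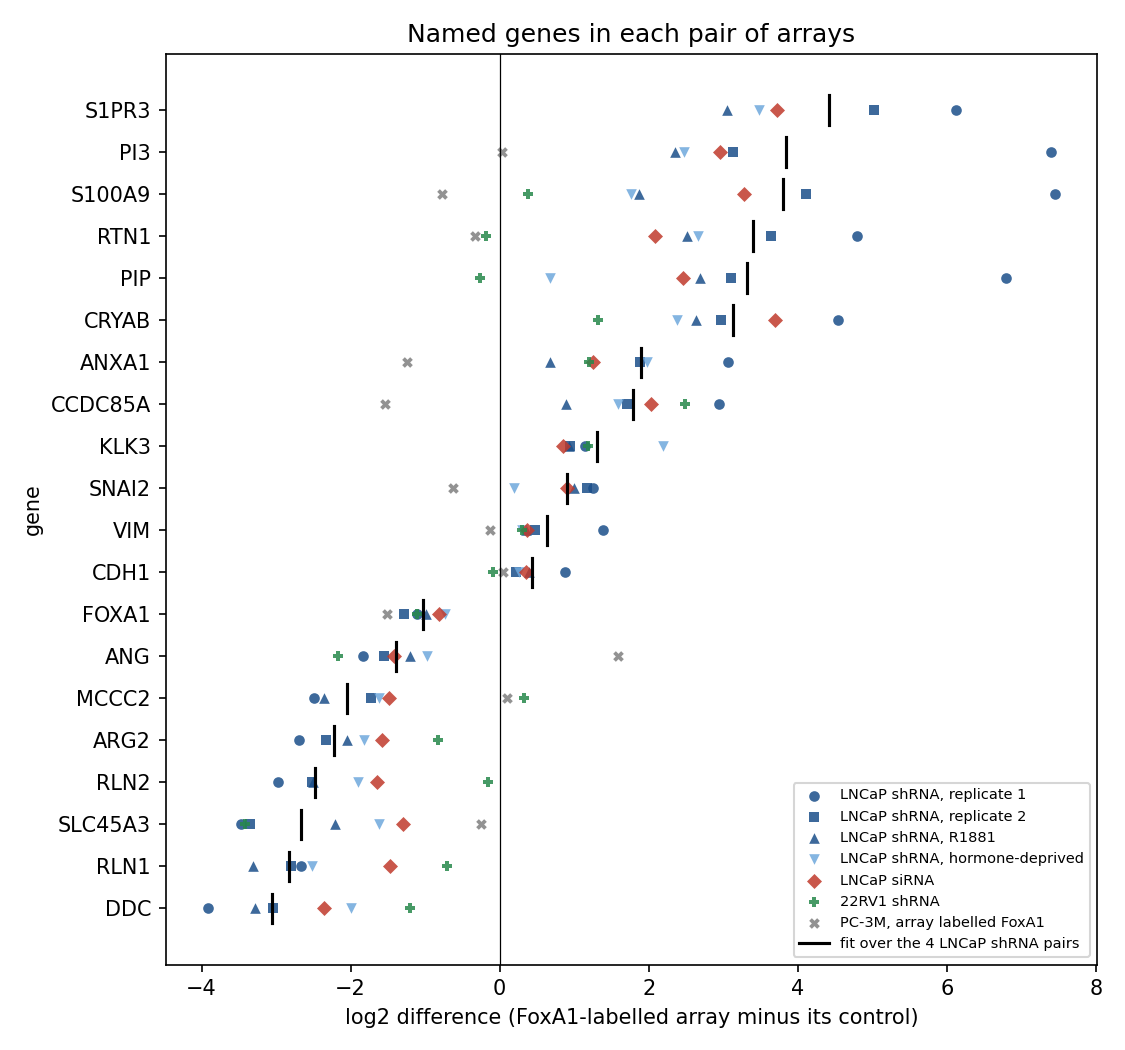
Log2 difference of each named gene (horizontal axis) in each pair of arrays, FoxA1-labelled array minus control; black bars mark the LNCaP shRNA fit and symbols the single pairs. FOXA1 lies below 0 in all 7 pairs, and the array labelled FoxA1 of PC-3M lies at least 2-fold the other way for ANXA1, CCDC85A and ANG.

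Cell-cycle genes fell. Among G1/S and DNA replication genes, 11 of 17 measured members fell and 0 rose, with a median log2 difference of -0.99 (camera adjusted p = 1.32e-09, and 0.449 with an estimated correlation); PCNA, the sliding clamp of the replication fork, fell by 0.89 (adjusted p = 0.0296), the helicase subunit MCM3 fell by 0.83 (adjusted p = 0.0256) and RRM1, of ribonucleotide reductase, fell by 0.86 (adjusted p = 0.03). Adjusted over the list alone, 16 fell. Among G2/M and mitosis genes, 6 of 19 fell and 0 rose, and 19 fell adjusted over the list alone, with a median of -1.37 (camera adjusted p = 1.32e-09, and 0.449 with an estimated correlation); the spindle motor KIF11 fell by 1.30 (adjusted p = 0.039), CENPF fell by 1.21 (adjusted p = 0.0351), the checkpoint kinase BUB1B fell by 1.12 (adjusted p = 0.0333) and the mitotic kinase PLK1 fell by 0.91 (adjusted p = 0.0379). These decreases were largest in the replicate 1 pair, KIF11 at -2.63 against -1.04, -1.04 and -0.50 and CENPF at -2.41 against -0.60, -0.95 and -0.87. Without replicate 1, KIF11 was at -0.86 (adjusted p = 0.0243) and CENPF at -0.81 (adjusted p = 0.0219), and PLK1 no longer passed the test (-0.65, adjusted p = 0.0611).

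Members of signalling, adhesion and motility lists rose. In the TGF-beta pathway list 4 of 13 members rose and 0 fell (6 rose adjusted over the list alone; median 0.59, camera adjusted p = 7.48e-05, and 0.355 with an estimated correlation): ID2 by 2.15 (adjusted p = 0.0203) and ID1 by 1.34 (adjusted p = 0.046), which block basic helix-loop-helix factors, the co-receptor TGFBR3 by 1.40 (adjusted p = 0.00679) and the pseudoreceptor BAMBI by 0.80 (adjusted p = 0.0434). Of the motility and matrix remodelling list, 4 of 20 rose and 0 fell, and 7 rose adjusted over the list alone (median 0.30, camera adjusted p = 0.00145, and 0.449 with an estimated correlation); they were the protease MMP7 at 3.12 (adjusted p = 0.0248), the laminin chain LAMB3 at 1.44 and at least 1.97-fold (adjusted p = 0.0434), ezrin (EZR) at 0.89 (adjusted p = 0.0185) and cortactin (CTTN) at 0.61 (adjusted p = 0.034). In the NF-kB and inflammatory list 1 of 10 rose, the chemokine CCL2 by 2.19 (adjusted p = 0.0391), and 4 rose adjusted over the list alone (median 0.82, camera adjusted p = 0.000451, and 0.464 with an estimated correlation); CXCL8 was 2.76 higher with an adjusted p of 0.0662. Both were largest in the replicate 1 pair, CCL2 at 4.66 against 1.13 to 1.55 in the others and CXCL8 at 6.59 against 1.00 to 1.82, and without replicate 1 CCL2 was 1.37 higher (adjusted p = 0.00411) and CXCL8 1.48 (adjusted p = 0.0068). In the hypoxia list 2 of 18 rose and 0 fell, NDRG1 by 1.64 (adjusted p = 0.0084) and the glycolytic ALDOA by 0.86 (adjusted p = 0.0369), and 4 rose adjusted over the list alone (median 0.38, camera adjusted p = 0.0101, and 0.672 with an estimated correlation); without replicate 1 the list had a camera adjusted p of 0.261. NDRG1 is also a member of the androgen-activated list. With an offset of 50 the TGF-beta median was 0.33 and the motility median 0.19. MMP7 was at 5.96 in the replicate 1 pair against 2.02 to 2.29 in the others and at 2.18 without replicate 1 (adjusted p = 0.000732). Without that replicate ID1 was 0.999 higher (adjusted p = 0.0634), BAMBI 0.54 (0.0581), CTTN 0.66 (0.0558) and ALDOA 0.69 (0.0836). These genes kept their direction, CTTN with no smaller difference, but no longer passed the test.

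Both mesenchymal and epithelial genes were among those that rose. In the mesenchymal list 2 of 9 rose and 0 fell, and 5 rose adjusted over the list alone (median 0.42, camera adjusted p = 0.00997, and 0.355 with an estimated correlation). SNAI2, the repressor known as Slug, rose by 0.90 (SE 0.18, adjusted p = 0.0261) and by 1.78 on a second probe (adjusted p = 0.0304), with pair differences of 1.25, 1.17 and 1.00 in replicates 1 and 2 and with R1881 and 0.19 in hormone-deprived medium. The actin-binding TAGLN rose by 0.83 (adjusted p = 0.0455), while vimentin (VIM) was 0.63 higher with an adjusted p of 0.0726, and 1.45 higher on a second probe with an adjusted p of 0.071. In the epithelial junction and keratin list 5 of 16 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (median 0.27, camera adjusted p = 0.0101, and 0.355 with an estimated correlation). The protease ST14 rose by 1.31 (adjusted p = 0.00982), keratin KRT19 by 1.17 (adjusted p = 0.0136), the epithelial factor GRHL2 by 0.97 (adjusted p = 0.0286) and desmoplakin (DSP) by 0.77 (adjusted p = 0.0273). E-cadherin (CDH1) was 0.44 higher with an adjusted p of 0.0925. Without replicate 1, SNAI2 was 0.79 higher on its first probe and DSP 0.62, and neither passed the test (adjusted p of 0.0611 and 0.0598).

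Genes that androgens are known to regulate went both ways. In the androgen-activated list 7 of 25 rose and 3 fell, and 9 rose and 5 fell adjusted over the list alone; the list was not called (camera adjusted p = 0.152), and its median of 0.25 turned to below 0 with median scaling, where it stayed 0.14 above the median of all genes. KLK3, which encodes the prostate-specific antigen, rose by 1.30 (SE 0.23, adjusted p = 0.0203) and the cation channel TRPM8 by 2.35 (adjusted p = 0.0118), against the decrease of SLC45A3. In the androgen-repressed list 5 of 8 fell and 1 rose, the same counts as adjusted over the list alone (median -1.38, camera adjusted p = 0.016, and 0.355 with an estimated correlation). UGT2B28 fell by 1.97 (adjusted p = 0.00434) and UGT2B11 fell by 1.61 (adjusted p = 0.015), both of a family that glucuronidates steroids, and BCHE, a cholinesterase, fell by 1.57 (adjusted p = 0.015), while CAMK2N1, an inhibitor of CaM kinase II, rose by 1.07 (adjusted p = 0.015). In the luminal prostate list 2 of 14 fell, FOXA1 and the luminal factor SPDEF (-1.09, adjusted p = 0.0361), and 0 rose; 2 rose and 5 fell adjusted over the list alone (median -0.22, camera adjusted p = 0.152). Without replicate 1, SPDEF was at -0.83 with an adjusted p of 0.0575.

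The remaining lists were not called. In the interferon list IRF7 rose by 0.54 (adjusted p = 0.0482) as 1 of 16 members (camera adjusted p = 0.334), and of 16 p53 targets 0 rose and 0 fell (camera adjusted p = 0.334); the medians of both, 0.072 and 0.042, turned to below 0 with median scaling, where they stayed 0.079 and 0.039 above the median of all genes. In the sterol synthesis list SC5D rose by 0.65 (adjusted p = 0.0422) as 1 of 16 (camera adjusted p = 0.889). In the unfolded protein response list the chaperone DNAJB9 rose by 1.13 (adjusted p = 0.0403) and XBP1 fell by 0.52 (adjusted p = 0.0372), of 18 members (median -0.010, mean 0.020, camera adjusted p = 0.889). Without replicate 1, IRF7, SC5D, DNAJB9 and XBP1 were at 0.55, 0.47, 0.93 and -0.46, with adjusted p of 0.0909, 0.0812, 0.0528 and 0.092. Of 5 neuroendocrine markers (camera adjusted p = 0.965), 2 basal markers and 4 fibroblast markers (camera adjusted p = 0.788) 0 passed the test. Of 6 leukocyte and endothelial markers VWF fell by 0.97 (adjusted p = 0.0107), and the list's median of 0.18 and mean of -0.016 differ in sign (camera adjusted p = 0.965, on the side of the mean). Adjusted over the list alone, 1 sterol gene rose, 1 unfolded protein response gene rose and 1 fell, 1 neuroendocrine gene fell, 1 leukocyte or endothelial marker rose and 1 fell, and 0 changed in the interferon, p53, basal and fibroblast lists. In the replicate 1 pair alone, the 10 measured markers of these other cell types had a median of 0.58, above 99.8% of random lists. Of the 18 lists tested, 9 were called; 0 were called with an estimated correlation, and fry, which asks only whether a list's own genes move one way, called 2, the androgen-repressed (adjusted p = 0.0318) and epithelial (adjusted p = 0.0447) lists. As a check on these calls, 7 of 34 splits of the arrays, the real one included, called at least as many lists.

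The numbered replicates, whose medium is not named, gave 312 genes by themselves, 196 of them higher, and 226 of the 312 were also called over the 3 media. S1PR3, undetected on both numbered shCtrl arrays, rose at least 29.9-fold (adjusted p = 0.00781) and SLC45A3 fell by 3.41 (adjusted p = 0.00781), in both pairs. SNAI2 rose by 1.21 (adjusted p = 0.0347), and FOXA1 was at -1.19 with an adjusted p of 0.0535. With all arrays, 2980 genes had an unadjusted p below 0.05. The limma count was 0 without shCtrl replicate 1 (1701 at an unadjusted p below 0.05), 0 without shCtrl replicate 2 (2084), 102 without shFoxA1 replicate 1 and 950 without shFoxA1 replicate 2. It was 0 from the deposited matrix (2719 at an unadjusted p below 0.05), 0 with no filter (3609), and 854, 591, 629 and 481 with no background correction, cyclic loess, median scaling and a filter on all 8 arrays. With each numbered pair as a block the count was 55, and with the numbers crossed, a setting chosen after seeing the data, 1097.

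The single pairs with R1881 and in hormone-deprived medium asked whether knockdown differences are seen with and without androgen; here and in the comparisons that follow there were no replicates, so values are given without a test except where the difference between media is named. With R1881, 215 genes were at least 2-fold higher and 216 at least 2-fold lower in shFoxA1. S1PR3 was 3.06 higher on the log2 scale, PGLYRP2, a peptidoglycan amidase, at least 7.28-fold, MYLK, the myosin light chain kinase, at least 4.86-fold, and CDKN2B, an inhibitor of cyclin D kinases, 2.79. RLN1 was at -3.31, DDC at -3.28, TARP at -3.18 and FOS, an immediate early gene, at least 4.53-fold lower. In hormone-deprived medium 132 genes were at least 2-fold higher and 76 lower. The diamine oxidase AOC1 was at least 10.5-fold higher, S1PR3 3.48, CYP1A2 3.29 and the kinase SGK1 3.08, and FOS was at least 14.8-fold lower, RLN1 -2.52, the early growth response gene EGR1 -2.43 and FOSB at least 4.21-fold lower.

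Cell-cycle genes were lower in both media. The G1/S median was -0.75 with R1881 and -0.59 without hormone, and the G2/M median -0.92 and -0.47, with 0 members higher in either pair. Androgen-repressed genes had medians of -0.58 and -1.08. Androgen-activated genes had a median of 0.10 with R1881, above 81.1% of random lists, and 0.47 in hormone-deprived medium, above 100% of them, where 17 of 24 members were higher; KLK3 differed by 0.93 and 2.19 and SLC45A3 by -2.21 and -1.62. NF-kB medians were 0.44 and 0.39, with 9 of 9 members higher in each, and 0.27 and 0.20 with an offset of 50. Hypoxia medians were 0.14 and -0.08, within the random range. The mesenchymal median was 0.35 with R1881, above the random range, with 6 of 7 members higher. In hormone-deprived medium the mesenchymal median was 0.19, within that range, with 7 of 9 members higher. TGF-beta medians were 0.46 and 0.22 and epithelial medians 0.39 and 0.21, and with median scaling the TGF-beta median turned to below 0 with R1881 and the epithelial median in both pairs. There they stayed above the median of all genes, TGF-beta by 0.47 with R1881 and epithelial by 0.33 and 0.24. Median scaling moved the median of all genes to -0.50 with R1881 and to -0.24 without hormone, and the genes at least 2-fold apart to 84 higher and 1481 lower with R1881 and to 73 higher and 177 lower without hormone.

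Genes called on the numbered replicates mostly kept their direction in the R1881 and hormone-deprived pairs. Of these 312, 97.8% had the same direction with R1881 and 85.9% in hormone-deprived medium, against 62.9% and 64.7% of genes not called. The descriptions call the R1881 arrays replicate 3, so the numbered replicates may have had R1881 too. The first share may then compare arrays of the same medium. The median of the raised genes was 0.95 with R1881 and 0.51 in hormone-deprived medium, and that of the lowered genes -0.84 and -0.47. A test of the difference in knockdown effect between media, in limma, whose spread comes only from the numbered replicates (2 residual degrees of freedom), called 0 genes in each of the 3 contrasts, with 602 genes at an unadjusted p below 0.05 for hormone-deprived against medium not named, 555 for R1881 against medium not named and 192 for hormone-deprived against R1881. Across all genes the R1881 and hormone-deprived knockdown differences had a Pearson correlation of 0.507.

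The R1881 and hormone-deprived arrays were also compared with each other in each shRNA line. Arrays with these labels were submitted in separate blocks, so a batch between them cannot be told apart from a response to R1881. In shCtrl, R1881 came with 169 genes at least 2-fold higher and 157 lower. TARP was 4.04 higher, GRM5P1 3.19, TRIM49D1 2.97 and TRIM49D2 at least 6.68-fold, and UGT2B17 was at -3.90, UGT2B15 at -3.45, SLC9A4 at -2.31 and LRRC31 at least 4.28-fold lower. All 25 measured androgen-activated genes were higher, with a median of 1.57, among them the protease TMPRSS2 at 2.46 and KLK3 at 2.20, and the androgen-repressed median was -1.40. G1/S genes were higher in 18 of 18 (median 0.55) and G2/M genes in 20 of 20 (median 0.53). In shFoxA1, 140 genes were at least 2-fold higher and 197 lower. SLC26A3 was at least 5.68-fold higher, the NDRG1 gene 3.13, HES6 3.08 and PGLYRP2 at least 7.05-fold, and AOC1 was at least 10.1-fold lower, DDC at -3.36, CYP1A2 at -3.12 and UGT2B17 at -2.96.

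In shFoxA1 the androgen-activated median was 1.25, with 23 of 24 members higher and FKBP5, a co-chaperone of steroid receptors, at 2.79 and KLK3 at 0.93. The androgen-repressed median was -2.13, with 0 of 8 higher. The G1/S median was 0.38 and the G2/M median 0.066, above 71.5% of random lists, and the hypoxia medians were 0.37 in shCtrl and 0.48 in shFoxA1. The difference between the lines was not tested beyond the contrast above. FOXA1 was -0.20 in shCtrl and -0.45 in shFoxA1, and median scaling, under which the first was 0.36, moved the median of all genes to 0.33 and the genes at least 2-fold apart in shCtrl to 685 higher and 108 lower. The mesenchymal median in shCtrl was -0.30 and became 0 in the deposited matrix.

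The siRNA pair used another way to lower FOXA1 in LNCaP. In siFoxA1, 299 genes were at least 2-fold higher and 162 lower. KRT16, a keratin of activated epidermis, was 5.00 higher on the log2 scale, its pseudogene KRT16P2 4.47, KRTAP13-2 at least 16.9-fold and CAMP, the cathelicidin antimicrobial peptide, at least 11.8-fold. UGT2B17 was at least 5.46-fold lower, DDC at -2.36 and the alcohol dehydrogenases ADH1A and ADH1C at -2.13 and -2.06. The near-identical sequences of KRT16 and KRT16P2 leave open which of them the probes read. G2/M genes were lower in 20 of 20 (median -1.0), FOXM1 among them at -1.29, and G1/S genes in 17 of 18 (median -0.69). NF-kB genes were higher in 13 of 16 (median 0.71), with CCL2 at 2.60 and CXCL8 at 1.98, hypoxia genes in 17 of 19 (median 0.56) and motility genes in 15 of 20 (median 0.55), with MMP7 at 2.45; with no background correction the NF-kB median was 0.40 and the motility median 0.23. The mesenchymal median of 0.20 lay within the random range. SNAI2 was 0.90 and 1.93 higher on its 2 probes, ACTA2, the smooth muscle actin, 2.95, KLK3 0.85, VIM 0.37 and 0.90 on its 2 probes and CDH1 0.35.

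The 22RV1 pair asked the same in another prostate cancer line. In shFoxA1, 240 genes were at least 2-fold higher and 192 lower. Secretagogin (SCGN) was 3.73 higher, the matrix protein EFEMP1 3.71, the homeobox gene HLX 3.08 and the pyruvate dehydrogenase kinase PDK4 3.05, and albumin (ALB) was at -4.47, SLC45A3 at -3.41 and the class II antigen genes HLA-DMB and HLA-DQB1 at -2.77 and -2.74. G2/M genes were lower in 20 of 20 (median -0.76), with KIF11 at -1.30 on its brightest probe and -1.01 on the probe of the LNCaP fit, and G1/S genes in 17 of 18 (median -0.55). The 4 measured basal markers had a median of 1.04, with KRT15 at least 3.96-fold higher and CAV1 at 1.95 on its brightest probe and -0.02 on the probe of the LNCaP fit, and the sterol synthesis median was -0.33, with INSIG1 at -1.29. With no background correction the basal median was 0.40, the sterol median -0.19, the epithelial median 0.11 and the p53 median 0.16. Of the lists called higher in LNCaP, the NF-kB, hypoxia, mesenchymal, TGF-beta and motility lists had medians of 0.067, 0.011, 0.052, 0.186 and 0.147, within the random range. The epithelial median of 0.24 and the p53 median of 0.24, with GDF15 at 1.83, turned to below 0 with median scaling, which moved the median of all genes to -0.41; they stayed 0.038 and 0.058 above it. KLK3 was 1.18 higher and KRT19 1.32. KLK3 lay near background, at a deposited intensity of 113.5 in shCtrl and 126.6 in shFoxA1, where the background modes were 89.9 and 83.4. SNAI2 was undetected, VIM was at 0.30 and 0.39 on its 2 probes and CDH1 at -0.09. With median scaling 1361 genes were at least 2-fold apart, 75 higher and 1286 lower, against 432.

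In PC-3M, 119 genes were at least 2-fold higher and 163 lower on the array labelled FoxA1, where FOXA1 was lower; directions are those of the labels. Interferon-stimulated genes were lower: the list median was -0.86, with 7 of 14 members at least 2-fold lower, IFIT1 and IFIT2 at -3.46 each, OASL at least 8.25-fold and IFIT3 at least 6.17-fold lower; with an offset of 50 the median was -0.56. The neuropeptide neurotensin (NTS) was at least 25.2-fold lower and the collagenase MMP13 at least 7.78-fold. The proteoglycan decorin (DCN) was at least 11.3-fold higher on its brightest probe and at -0.19 on the probe of the LNCaP fit, the prostaglandin dehydrogenase HPGD at least 10.6-fold, the cadherin CDH12 3.60 and complement C5 3.58. Hypoxia genes were lower in 16 of 19 (median -0.31), with NDRG1 at -1.30, and sterol synthesis genes higher in 14 of 16 (median 0.42), with DHCR7 at 0.85. P-cadherin (CDH3) was at -2.64 and CXCL8 at -2.18, while SPDEF was at least 2.20-fold higher and KRT8 1.32. The luminal median was -0.63, the G1/S median 0.099 and the G2/M median 0.065. The TGF-beta median was 0.36, with 11 of 13 members higher, and the epithelial median 0.24. The motility, NF-kB and neuroendocrine medians were -0.23, -0.40 and -0.33. These last medians, TGF-beta and epithelial included, lay outside the random range. On the array labelled FoxA1, SNAI2 was at -0.63 and -0.39 on its 2 probes, VIM at -0.12 and -0.50 and CDH1 at 0.04.

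**Figure D2:**
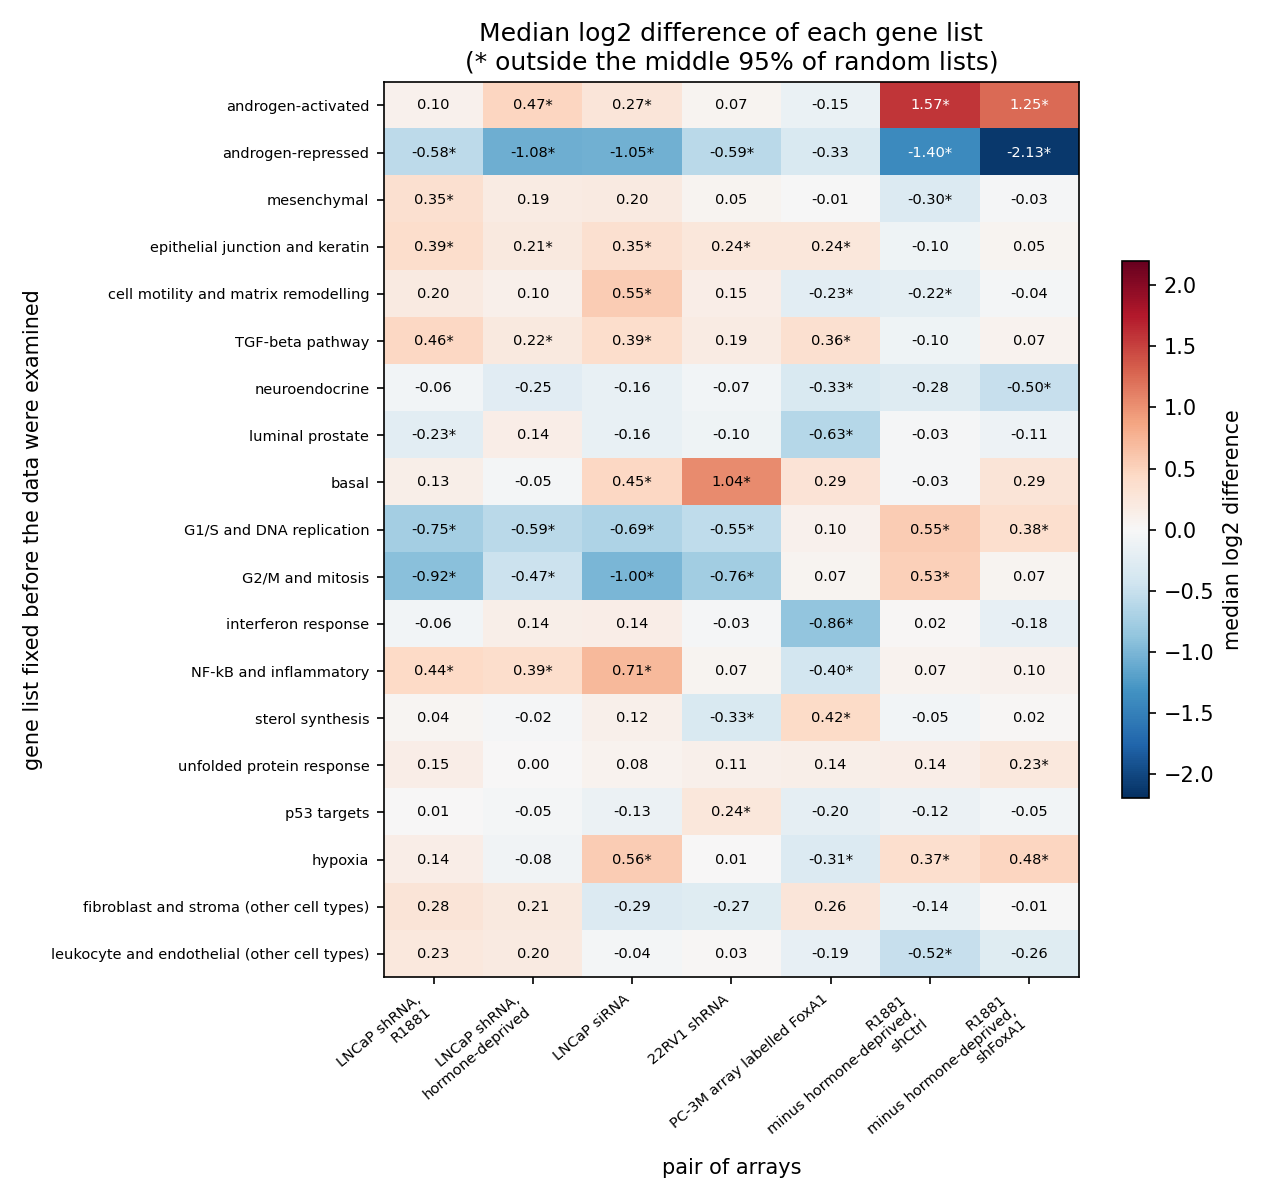
Median log2 difference of each gene list (vertical axis) in each pair of single arrays (horizontal axis), with asterisks where it lies outside the middle 95% of matched random lists. G1/S and G2/M medians lie below 0 in the 4 FoxA1 knockdown pairs. Median scaling alone, which also lowers the median of all genes, turns the epithelial medians of the R1881, hormone-deprived and 22RV1 knockdown pairs below 0. It does the same to the TGF-beta median with R1881 and the p53 median in 22RV1. All of these stay above the median of all genes.

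The models were compared through the 939 genes called in LNCaP over the 3 media. In the siRNA pair 96.4% of 935 called genes had the same direction, against 69.3% of genes not called, with a Pearson correlation of 0.747 across genes. In 22RV1 the share was 79.2% of 888, against 60.8%, with a correlation of 0.409. In PC-3M, 46.7% of 805 called genes had the knockdown direction on the array labelled FoxA1, against 49.1% of genes not called, with a correlation of -0.039; from the deposited matrix the share was 52.7%. Of 884 genes called and compared in both, 39 were at least 2-fold apart the same way in the siRNA and 22RV1 pairs, 26 higher and 13 lower, against a share of 0.298% among genes not called. ANXA1, the annexin that inhibits phospholipase A2, rose by 1.90 in LNCaP (at least 2.84-fold, SE 0.34, adjusted p = 0.0203) and was at 1.26 with siRNA (at least 2.35-fold), 1.20 in 22RV1 and -1.25 on the PC-3M array labelled FoxA1. CCDC85A rose by 1.79 (at least 2.12-fold, SE 0.31, adjusted p = 0.0201), with 2.04 (at least 3.30-fold), 2.48 and -1.53, and the ribonuclease angiogenin (ANG) fell by 1.39 (SE 0.18, adjusted p = 0.00854), with -1.41, -2.17 and 1.58. Of 29 of these genes measured in PC-3M, by the labels 15 went the other way, these 3 by at least 2-fold, and 14 the same way, BCHE (-1.48) and the phosphatase DUSP2 (1.17) by at least 2-fold; were the arrays swapped, both sets would change places.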

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

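Both tests on the PC-3M pair, and the test for a swapped medium label, were chosen after the result was seen.

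Differences between groups drew attention to 2 genes that passed the test in LNCaP, were at least 2-fold apart one way over the LNCaP shRNA arrays, had that sign in all 5 LNCaP pairs and were at least 2-fold apart the other way in 22RV1. FAM110B rose by 1.63 in LNCaP (adjusted p = 0.00772), was at 0.034 with siRNA and at -1.31 in 22RV1. TSPAN13, a tetraspanin, rose by 1.45 (adjusted p = 0.0028), was at 1.42 with siRNA and at -1.06 in 22RV1. The difference between the lines was not tested for either gene, because 22RV1 has 1 array per group. Between media, 2 genes were at least 2-fold lower in the R1881 knockdown pair and at least 2-fold higher in the hormone-deprived pair: TRIM49C, at -1.42 and 1.05, and TRIM51, at -1.75 and 1.03. Over all genes the test of that difference called 0 genes in limma, with 192 at an unadjusted p below 0.05; for these genes alone it was not tested. Among the 6288 kept probes with no single gene name, which no comparison used, 200 passed the same test over the 3 media, 112 higher and 88 lower.

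The LNCaP gene count was set against other splits of the 8 arrays. Of 35 splits 1 could not be fitted; in the other 34, only 1, the real one, gave as many genes, with 939 against a highest other count of 229. Most of these splits are uneven over media and share variation with the medium term. The 12 splits even over media gave at most 0 genes apart from the real one, and are too few for a share under 0.05. For the list calls 7 of the 34 splits gave as many, with 9 in the real split and 10 in the highest other, so chance is not excluded there.

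The first pattern weighed is FOXA1 at -1.51 on the PC-3M array labelled FoxA1. If both arrays were swapped, genes called in LNCaP would move in the knockdown direction on that array more often than other genes, if PC-3M responds to FOXA1 as LNCaP does. On that array 46.71% did, against 49.09% of genes not called, but from the deposited matrix 52.7% did, against 47.4%, so a swap cannot be told apart from a right label. A probe that does not read the introduced copy would need another FOXA1 probe to test it, and the table holds 1, so this cannot be told apart either. No biological explanation was tested.

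The second pattern is the larger differences of the replicate 1 pair, with an SD over all genes of 0.807 against 0.52, 0.442 and 0.362 in the other pairs. With the numbered shCtrl arrays, shFoxA1 replicate 1 correlated at 0.917 and 0.933, and shFoxA1 replicate 2 at 0.955 and 0.965. The larger differences thus go with the shFoxA1 replicate 1 array against either numbered control. On that shFoxA1 array, another response in place of the shared one is argued against. Of the 629 genes called without replicate 1, 96.66% moved the same way in this pair, at a slope of 1.71 on the mean of the other 3 pairs. A further response added to the shared one cannot be excluded, since these genes were called from the other arrays. Array quality may contribute: 35.66% of probes were detected on the shFoxA1 array, within the range of the others, but 34.3% on its shCtrl partner, below all others. The low share on that partner has no bearing on the lower correlation of shFoxA1 replicate 1 with shCtrl replicate 2, at 0.933. RNA of other cell types may contribute too: their 10 markers had a median of 0.5753, above the random range of -0.341 to 0.359. Most of them lie near background, and VWF at -0.67 goes the other way. CD68, at 1.25 in this pair, was detected on all 4 shCtrl arrays, at a mean log2 intensity of 8.45. CD68 was also 0.23 to 0.70 higher in the other LNCaP shRNA pairs and 1.06 higher with siRNA. Its rise therefore cannot tell RNA of other cell types from the knockdown. A stronger knockdown in that pair was not tested as a cause, and FOXA1 was at -1.10 there against -1.28 in replicate 2.

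The third pattern is the androgen-activated list on the hormone-deprived shFoxA1 array, with a median of 0.47 over its partner. A culture that in fact held R1881 is argued against: between both shFoxA1 arrays the list still had a median of 1.25, against 1.57 in shCtrl. Residual androgen in that culture would raise the members in the order in which R1881 raises them; over 25 members the Spearman correlation was 0.1431 (two-sided permutation p = 0.494), which decides nothing. A change of this list with FoxA1 loss in hormone-deprived medium stays open as a hypothesis, untested with 1 array per group. Over the 3 media the list was not called (camera adjusted p = 0.152), and the limma tests between media called 0 genes.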

How the results depend on the processing

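The crossed pairing, the setting without replicate 1, and the R1881 and hormone-deprived pairs alone were chosen after seeing the data. The 939 genes over 3 media became 1456 with median scaling (247 higher, 1209 lower), 188 from the series matrix (107 and 81), 265 with no filter and 313 at 2-fold or more. They became 123 without the medium term, 236 without both the medium term and the hormone-deprived pair, 478 with these 6 arrays and a replicate block, 801 with them and the medium term, and 52 without the R1881 pair. Leaving out single arrays or replicate 1 gave 121 to 737. With each pair as its own replicate block the count was 527. The deviations of same-numbered arrays correlated at -0.173, which gives no sign that the numbers pair the arrays. The crossed pairing gave 1138 genes over 3 media and 1097 with medium not named. The other settings gave 740 to 1350 and stayed within 1.5 times.

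With medium not named, the 312 genes became 854 with no background correction, 591 with cyclic loess, 629 with median scaling, 0 from the series matrix, 0 with no filter, 481 with detection on all 8 arrays, and 55 with a replicate block; leaving out single arrays gave 0 to 950, where the lone array of a group is assumed to vary like the others, and the other settings stayed within 1.5 times. Of 9 list calls, 0 were left with an estimated correlation and 2 with fry. FOXA1 over 3 media was at -1.02 (adjusted p = 0.0554) without the medium term and at -1.04 (adjusted p = 0.0678) without the R1881 pair, against 0.00282 to 0.0453 elsewhere.

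For single pairs, in the order R1881 knockdown, hormone-deprived knockdown, siRNA, 22RV1, PC-3M, R1881 response in shCtrl and in shFoxA1, the main counts of genes 2-fold apart were 431, 208, 461, 432, 282, 326 and 337. With no background correction they were 247, 112, 143, 142, 182, 210 and 207; with an offset of 50, 220, 100, 223, 208, 146, 184 and 182; at 1.5-fold, 1726, 1006, 1786, 1973, 1241, 1402 and 1434. From the series matrix they were 714, 414, 740 and 773 for the first 4 and 564 and 610 for the R1881 responses. Median scaling gave 1565 (84 higher, 1481 lower) in the R1881 knockdown, 1361 (75 and 1286) in 22RV1 and 793 (685 and 108) in the shCtrl response; it moved FOXA1 to -1.61 with R1881, -0.99 in hormone-deprived medium and -1.67 in 22RV1, and turned its shCtrl response from -0.20 to 0.36, where the median of all genes moved to 0.33. The same scaling gave 73 higher and 177 lower in the hormone-deprived knockdown (main 132 and 76) and 301 higher and 293 lower with siRNA (main 299 and 162). The other settings of the single pairs stayed within 1.5 times. From the series matrix, the share of called genes with the knockdown direction was 72.3% in 22RV1 and 52.7% in PC-3M, which turned from below to above 50%. Of the recomputed values of 55 named genes of the LNCaP fit, 769 kept their side of the threshold, 370 lost it, 1 gained it and 0 reversed; of those of 230 named values in single pairs, 1034 stayed within the replicate spread of 0.212, 545 moved further and 1, FOXA1 above, reversed. Of the recomputed list calls, 46 kept the call, 17 lost it and 0 reversed. A slide block was not run because the column names give no slide. The left-out settings also have fewer arrays. The cause of the changes was not tested for any setting. Genes near background, where 34.3 to 42.6% of probes were detected on the LNCaP shRNA arrays, are limited by signal over background.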

Other observations

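Among the 39 genes at least 2-fold apart the same way in siRNA and 22RV1, chosen after their values were seen, SGK1, a serum and glucocorticoid regulated kinase, rose by 2.76 in LNCaP (adjusted p = 0.00386) and was at 2.74 with siRNA and 1.28 in 22RV1. The carbonic anhydrase CA4 rose by 2.03 (adjusted p = 0.0042), with 3.40 and 2.47, and the cytokine signalling inhibitor SOCS2 by 1.37 (adjusted p = 0.0284), with 1.30 and 2.69. The neuropeptide gene NMU fell by 1.75 (adjusted p = 0.0201), with -1.28 and -1.34. In the PC-3M pair the pioneer factor FOXA2 was at -2.44 and the collagen chain COL1A2 at -2.04 on the array labelled FoxA1.

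Of 314 called genes with another kept probe, 17 had a probe of the opposite sign, and 0 of these probes passed the test.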
